A study of Naumovozyma castellii with 9 samples.

How the data were processed

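The libraries hold strand-specific total RNA of the budding yeast Naumovozyma castellii, a relative of Saccharomyces cerevisiae. There were 9 libraries, 3 each of a MATalpha wild type (WT), of a strain lacking UPF2 (upf2-delta) and of a strain lacking UPF3 (upf3-delta). Per the labels, cells grew in rich medium at 25 °C to an OD600 of 0.5, 1 µg of total RNA per sample received 2 µl of a 100-fold diluted ERCC spike-in mix, and ribosomal RNA was depleted before stranded libraries were made. The labels number the samples 1 to 3 within each genotype without saying whether these were separate cultures. The p-values of the fits therefore measure the spread between these samples, which may be technical, and permutation p-values over features do not measure it.

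The submitters' processing notes name Trim Galore, HISAT2 2.2.0, featureCounts 2.0.0 and DESeq2, with no role, order or parameters. The genome build and the strand setting of the counting are not given in the sources used here. The deposited values are a signal, a density of reads per nucleotide of each feature scaled per library, for 8585 features with chromosome, start, end and strand. Coordinates are printed as that table gives them. The density times the feature length, divided by 1 step per library, was a whole number for 100% of values within a tolerance of 0.01, so reads per feature were recovered. The steps equalled the inverse of median-ratio size factors over the 37 snoRNA features in all 9 libraries. This identity comes from the values, not from a label. Scaling on snoRNAs makes every change relative to that class. A median-ratio scaling over mRNAs would shift all log2 fold changes down by the difference between the scalings, 0.12 in upf2-delta against WT, and by -0.01 in upf3-delta against WT.

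Recovered reads totalled 39811424, 52526389 and 43641109 in WT, 42423619, 43210345 and 43811414 in upf2-delta and 29678395, 29677183 and 25143181 in upf3-delta. For the fold bounds of the deleted genes, 0 reads were replaced by a floor of 3 reads per library, and floors cover counting error only. Elsewhere a density of 0 was kept as 0. Replicate pairs differed by far more than sampling noise: chi-square per degree of freedom, over features with at least 10 reads in the pair, ran from 10.3 to 317. The pairs of upf3-delta were the closest, and upf2-delta 1 and 3 were the farthest apart.

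Gene symbols came from a RefSeq table of assembly ASM23734v1. Of 5595 mRNA features, 5584 matched it by locus tag and 4492 had a symbol. The remaining features are 961 XUTs (Xrn1-sensitive unstable transcripts), 1274 CUTs (cryptic unstable transcripts), 146 SUTs (stable unannotated transcripts), 555 tRNA, 37 snoRNA, 14 rRNA and 3 snRNA features. Of the XUTs, 324 overlapped a CUT on the same strand and can share its reads, while 0 XUTs and 0 CUTs overlapped an mRNA on the same strand. Among the features, 257 repeat the position of another, of which 255 are tRNA features.

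Densities were tested with limma 3.58.1 in R 4.3.3 on log2(density + 0.03), with an empirical Bayes mean-variance trend, genotype as the only term and all 9 libraries in 1 fit. The pseudocount is the 10th percentile of all positive values, rounded, and features with a mean density of at least 0.03 were tested (7710 of 8585). Fold changes are on this scale and understate changes of features near the pseudocount, while folds printed in the text are ratios of mean densities. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested features, with calls at 0.05. The test was fixed before the data were examined, as were the samples, the alternatives listed further on except those said to be added, the gene lists and the rule for named genes. The plan gave a count model only for a table of whole-number counts. The deposited values are not counts, so neither that model nor its count-based alternative was run.

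The named genes are, for each comparison with WT, the 10 coding features with a symbol that rose most and the 10 that fell most, among those called with all 3 mutant libraries beyond all 3 WT libraries. The rule adds the 5 non-coding features that rose most and the 5 that fell most, the NMD factors, and up to 4 members of each list with the largest absolute change. For upf3-delta against upf2-delta it takes the 5 largest in each direction, among non-coding features and coding features with a symbol. Genes outside this rule are said to have been chosen after their values were seen.

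Of 22 gene lists written by symbol, 21 had at least 3 tested members and 1, RNA interference, matched 0. They covered NMD factors, decapping and 5'-to-3' decay, the exosome with SKI and TRAMP, known NMD targets of S. cerevisiae, pyrimidine, arginine and other amino acid biosynthesis, and histones. Further lists were ribosome biogenesis, translation factors, ribosomal proteins, mitochondrial ribosomal proteins, glycolysis, respiration, general stress response, phosphate and iron uptake, and galactose and allantoin catabolism. Lists of mating type or cell state were a-specific genes, alpha-specific genes (the mating type of these strains), and meiosis and sporulation. Another list held telomere maintenance genes. Lists and feature classes were tested with limma's camera with a preset correlation of 0.01, and again with an estimated correlation. Camera compares members with the other features, so a lower rank need not mean a fall. Lists share members: EST1, EST2, EST3, STN1 and TEN1 are in both the NMD target and the telomere lists, and CPA1 is in both the NMD target and the arginine lists.

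Correlations between the deletions were set beside 100 simulations of unchanged groups, since both use the same WT libraries. Every library, WT included, was drawn around the WT means with noise independent across features. Non-coding features overlapping an mRNA on the opposite strand by at least 1 nt were paired with it and tested by permutation with 100000 resamples.

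Data were simulated with the WT means, the snoRNA size factors and an assumed spread that was equal and independent across features. All mRNAs changed 2-fold up or down were called in upf2-delta against WT (100% of each). In upf3-delta against WT, 98% of features raised 2-fold and 96% of those lowered to 0.5 were called. The shares of calls that had not been planted were 4.31% and 7.51%, over 7262 features. The real replicates also differed along a shared component that was not simulated here, so these shares do not give the power or error of the fit.

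Alternatives were other pseudocounts and filters, a median-ratio scaling over coding features, quantile normalization, the replicate number as a block, no trend, fits of 6 libraries, a threshold of 0.01, an estimated correlation, a wider antisense overlap and each library left out. Added after seeing the data were voom on the recovered reads, the main component of variation within genotypes as a covariate, alone and with median-ratio scaling, 1 feature per position, and WT 1 and upf2-delta 1 left out together. Scaling on the ERCC spike-ins was not run, and spike-in values were not analysed here. The authors' mean columns were not used. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.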

Results

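Strand-specific total RNA was sequenced from 3 genotypes of the yeast Naumovozyma castellii, with 3 libraries each of WT, upf2-delta and upf3-delta. UPF2 and UPF3 encode cofactors of nonsense-mediated decay (NMD), the pathway that degrades mRNAs with a premature stop codon. UPF2 carries the symbol NMD2 in the gene table. The question was which coding and non-coding transcripts respond to the loss of each cofactor, and the values are scaled read densities of annotated features. Depth ranged from 39811424 to 52526389 reads in WT, from 42423619 to 43811414 in upf2-delta and from 25143181 to 29678395 in upf3-delta. mRNAs took 87.5% ± 0.826 of the reads in WT, 87.4% ± 0.930 in upf2-delta and 87.9% ± 0.412 in upf3-delta (SD, n = 3). XUTs took 0.887% ± 0.0729 in WT, 1.52% ± 0.176 in upf2-delta and 1.25% ± 0.0330 in upf3-delta (SD, n = 3). CUTs took 0.288% ± 0.0217, 0.497% ± 0.0372 and 0.443% ± 0.0184 in the same order (SD, n = 3).

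Each deleted gene was read first, as a check of the labels. NMD2 (NCAS_0H01720, chromosome 8, 326096 to 329329, minus strand) had 4583, 6418 and 5984 reads in the WT libraries and 0 reads in each of the 3 upf2-delta libraries. Its density was 1.36 ± 0.0829 in WT (SD, n = 3), so it was at least 1378-fold lower in upf2-delta, taking a floor of 3 reads per library. In upf3-delta it was 1.23 ± 0.119 (SD, n = 3), a difference from WT that did not pass the test (log2 -0.14 ± 0.13 SE). UPF3 (NCAS_0B05240, chromosome 2, 973081 to 974370, plus strand) had 1720, 2467 and 1811 reads in WT and 0 reads in each of the 3 upf3-delta libraries. It was at least 302-fold lower there than in WT, where its density was 1.21 ± 0.165 (SD, n = 3). UPF3 rose in upf2-delta to 2.01 ± 0.384 (SD, n = 3), a log2 change of 0.71 ± 0.16 SE (adjusted p = 0.00373).

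With the deposited snoRNA scaling, 2020 features were higher and 60 lower in upf2-delta than in WT, against 2086 and 1083 with median-ratio scaling and 1538 and 2627 with quantile normalization, so the balance of directions depends on the scaling. The telomerase subunit genes EST1, EST2 and EST3 rose 5.39-fold, 4.36-fold and 4.58-fold, and EST1 went from a density of 0.541 ± 0.0522 to 2.91 ± 0.234 (SD, n = 3). The allantoin genes DAL5, DAL3, DAL7 and DAL1 rose between 6.50-fold and 8.58-fold, and SPO22 and REC107, which act in meiotic recombination, rose 8.28-fold and 11.2-fold. The mating genes FUS1 and FUS3 fell by 1.81 ± 0.24 and 1.10 ± 0.15 on the log2 scale (SE). XUTs, the antisense and intergenic transcripts degraded by Xrn1, had a median log2 change of 1.00 (adjusted p = 4.13e-21, and adjusted p = 0.103 with an estimated correlation).

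Of the 7710 tested features, the 2020 higher and 60 lower with the snoRNA scaling included 1256 and 8 that changed at least 2-fold. The lower count was 1083 with median-ratio scaling and 2627 with quantile normalization. Under settings chosen after seeing the data it was 653 with the main component of variation within genotypes as a covariate, 1935 with that covariate and median-ratio scaling, and 153 without WT replicate 1 and upf2-delta replicate 1 together. By class, 1210 of 5450 mRNAs were higher and 39 lower, 493 of 785 XUTs were higher and 2 lower, and 305 of 889 CUTs were higher and 5 lower. Of 104 SUTs, 4 were higher and 4 lower. Of 428 tRNA features, 6 were higher and 10 lower, or 3 and 5 over their 236 distinct positions, and 2 of 14 rRNA features were higher. limma called 0 of 37 snoRNAs, and 0 had an unadjusted p under 0.05. The 3 libraries of each genotype did not overlap for 35.5% of features with the snoRNA scaling (2470 higher, 265 lower). By chance, with no offset common to many features, 10% would not. The CUT median was 0.40 (adjusted p = 0.0116, and adjusted p = 0.545 with an estimated correlation), and quantile normalization turned it to -0.13. The CUT call was lost without WT replicate 2 (0.42) and without upf2-delta replicate 3 (0.45). SUTs (median -0.07) and tRNAs (-0.17) lay below the other features (adjusted p = 3.77e-05 and 5.73e-11). With an estimated correlation these became adjusted p = 0.265 and 0.299. Over the WT mean, tRNA medians were 0.28, 0.05 and -0.76 in upf2-delta 1, 2 and 3, so only upf2-delta 3 lay below it. These class tests count repeated tRNA positions as separate members. The scaling holds the snoRNA median near 0 by construction (-0.02), so the rank of that class was not interpreted in any comparison. The mRNA median was 0.04 and the mean 0.26, while the test ranked mRNAs below the other classes (adjusted p = 0.00252, and adjusted p = 0.679 with an estimated correlation), and the median turned to -0.07 with median-ratio scaling and -0.17 with quantile normalization. The mRNA call was lost without WT replicate 2 (0.08). rRNA features had a median of 0.03 that did not pass the test (adjusted p = 0.307), with medians of 1.28, -0.03 and -0.62 in the 3 upf2-delta libraries, and the median turned to -0.08 and -0.04 with those scalings. Copies of tRNA and rRNA genes are nearly identical, so their values are uncertain.

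**Figure D1:**
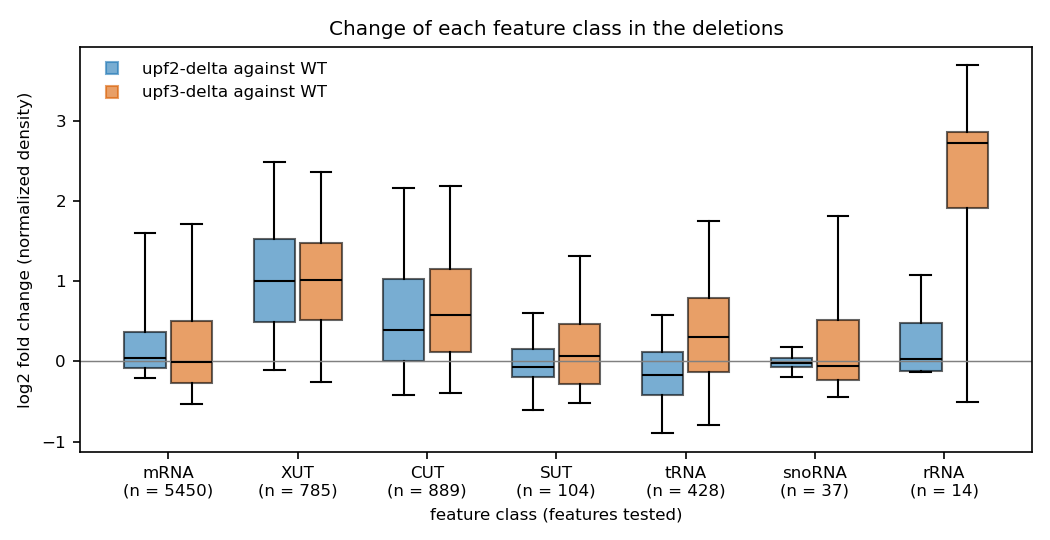
Log2 fold changes by feature class in each deletion against WT, as boxes from the lower to the upper quartile with the median, and whiskers at the 5th and 95th percentiles. XUT medians were 1.00 in upf2-delta and 1.01 in upf3-delta, and CUT medians were 0.40 and 0.58, which quantile normalization turned to -0.13 and -0.06.

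The coding genes that rose most in upf2-delta were led by RMD6, a gene required for sporulation (NCAS_0J00680, chromosome 10, 104201 to 104785). It rose 17.3-fold, from 0.502 ± 0.0809 to 8.71 ± 4.04 (SD, n = 3; adjusted p = 3.73e-08). TAH1, a cofactor of the Hsp90 chaperone (NCAS_0D04500, chromosome 4, 855490 to 855855), rose 12.5-fold, from 0.704 ± 0.106 to 8.80 ± 1.33 (SD, n = 3; adjusted p = 1.57e-09). MAK31, a subunit of an N-terminal acetyltransferase, rose by 3.54 ± 0.14 on the log2 scale (SE) and lies opposite CUT0195. SLO1, the sporulation gene ISC10, TVS1 and SGN1 rose 9.74-fold, 9.68-fold, 9.53-fold and 7.50-fold. TAH1 and TVS1 are neighbours on one strand, as are SLO1 and ISC10. Among non-coding features, CUT0912 rose by 3.25 ± 0.21 on the log2 scale (SE). CUT1114 and XUT0849 (chromosome 8, 22466 to 23293 and 22423 to 23328) rose by 3.24 and 3.22. They overlap each other and lie opposite DLD3, so they can share reads. XUT0541 and CUT0642 each rose by 3.06.

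Fewer genes fell. After NMD2, the largest falls were those of FUS1, which acts in cell fusion (density 0.286 ± 0.0778 to 0.0587 ± 0.00756, SD, n = 3; adjusted p = 4.95e-05), and the B-type cyclin gene CLB1 (log2 -1.16 ± 0.17 SE). FUS3, the MAP kinase of the mating response, and KAR4, a regulator of nuclear fusion, changed by -1.10 ± 0.15 and -0.64 ± 0.15 (SE). NRG1, GTT1, GSY1 and DDR48 changed by log2 values from -0.78 to -0.62. The glucokinase gene GLK1 fell by 0.86 ± 0.22 (SE), a call lost without WT replicate 1 (-0.77). Of the non-coding features, the tRNA feature ENSRNA049593095 fell by 0.95 ± 0.17 (SE). CUT1041 fell by 0.86 ± 0.23 (SE), a call lost without WT replicate 3 (-0.71) or upf2-delta replicate 2 (-0.69), and 3 further tRNA features each lost their call without at least 4 of the libraries in turn. The sum of 60 lower features became 209 without upf2-delta replicate 1 and 35 without upf2-delta replicate 2.

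**Figure D2:**
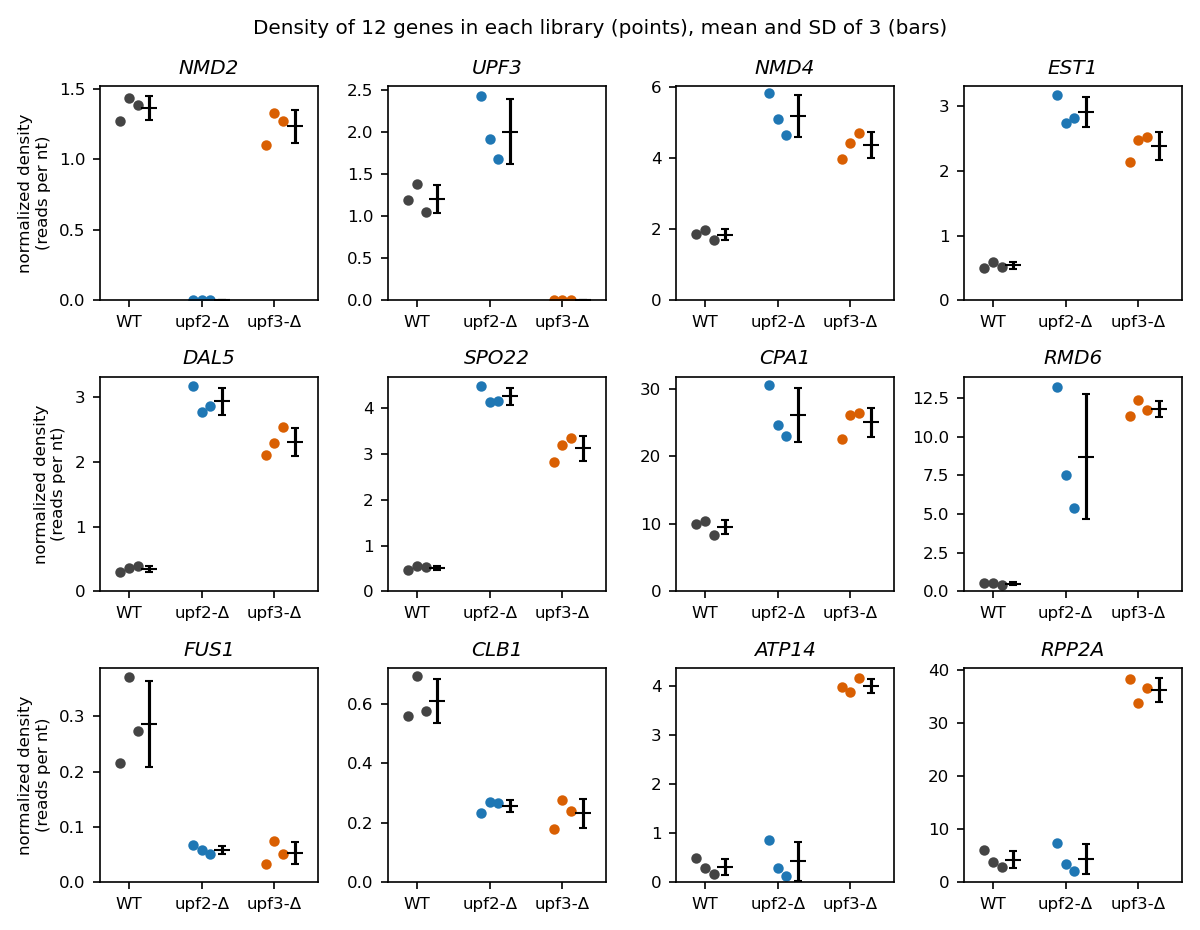
Scaled read density of 12 genes on linear axes from 0, with a point per library and the mean and SD of 3 libraries per genotype. EST1 went from 0.541 in WT to 2.91 in upf2-delta and 2.38 in upf3-delta, while FUS1 went from 0.286 to 0.0587 and 0.0530.

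Of the NMD factors, 4 of 5 rose in upf2-delta and NMD2 was absent. NMD4, EBS1 and NAM7, the gene of the Upf1 helicase, rose by 1.47 ± 0.12, 0.65 ± 0.12 and 0.47 ± 0.12 (SE), and the NAM7 call was lost without WT replicate 1 (0.42) and without WT replicate 3 (0.42). The list's median was 0.65, also with NMD2 at its bound, and its mean of -0.45 came from the deleted gene. It did not pass as a list (adjusted p = 0.620), and its test passed with a direction opposite to that of the full data without upf2-delta replicate 3 (median 0.63). This list test includes the deleted gene, which weighs against the other 4 members, and it was not run without that gene. Known NMD targets of S. cerevisiae rose together, 8 of 9 members with a median of 1.5 (adjusted p = 3.24e-07, and adjusted p = 0.584 with an estimated correlation). ALR1, a magnesium transporter gene, rose 3.23-fold, the arginine gene CPA1 2.73-fold and STN1 2.87-fold. PPR1, the member that did not pass (-0.05), was looked up after the counts were seen. Genes of meiosis and sporulation rose in 11 of 17 cases, 12 when adjusted over the list alone, with a median of 0.86 (adjusted p = 5.12e-06, and adjusted p = 0.584 with an estimated correlation). Folds are ratios of mean densities, which exceed the fitted change for genes near the added constant such as HOP2. HOP2, RED1 and MSH4, which act in pairing and recombination of meiotic chromosomes, rose 10.1-fold, 7.48-fold and 5.84-fold. Telomere maintenance genes rose in 6 of 11 cases, 7 when adjusted over the list alone (median 1.07, adjusted p = 0.000378, and adjusted p = 0.782 with an estimated correlation). Galactose and allantoin genes rose in 6 of 10 cases (median 1.37, adjusted p = 0.000787, and adjusted p = 0.782 with an estimated correlation). Arginine genes rose in 5 of 7 cases (median 0.65, adjusted p = 0.0170, and adjusted p = 0.782 with an estimated correlation), with ARG8 at 3.92-fold, ARG3 at 2.61-fold and ARG1 at 1.61-fold, and ARG1 lost its call without WT replicate 3 (0.58).

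Pyrimidine genes rose in 4 of 7 cases, with URA3 at 2.34-fold and URA1 at 2.28-fold, while the list did not pass (median 0.84, adjusted p = 0.131) except with quantile normalization (0.78). Other amino acid genes rose in 9 of 35 cases (median 0.15, adjusted p = 0.339), led by the sulfate assimilation genes MET16 (4.77-fold) and MET3 (2.57-fold). Among a-specific genes, normally silent in alpha cells such as these, the receptor gene STE2 rose 3.32-fold, BAR1 2.28-fold and STE6 1.69-fold, and AGA2 did not pass (-0.59). That list did not pass (3 of 4 higher, median 0.89, adjusted p = 0.112). Of 3 alpha-specific genes SAG1 fell by 0.48 ± 0.17 (SE; adjusted p = 0.0494), a call lost without WT replicate 2 or 3 (-0.40 and -0.41), without upf2-delta replicate 2 or 3 (-0.49 and -0.33), or without any upf3-delta replicate (-0.48 in each case). The list did not pass (median 0.00, mean -0.05, adjusted p = 0.392), and its median was -0.11 with median-ratio scaling.

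Camera ranked 8 lists below the other mRNAs in upf2-delta, with changes close to 0. The mRNAs had a median change of 0.04 and a mean of 0.26, so unchanged lists can rank low. Such a rank alone does not show a fall. Ribosomal protein genes had a median of -0.06 (adjusted p = 0.000716), glycolysis genes -0.03 (adjusted p = 0.0294) and translation factor genes -0.05 (adjusted p = 0.0349), and quantile normalization turned the test's direction for all 3. None of these calls held with an estimated correlation (adjusted p = 0.782). The others were ribosome biogenesis (-0.06, adjusted p = 0.00764), decapping and 5'-to-3' decay (-0.11, adjusted p = 0.0180), mitochondrial ribosomal proteins (median 0.00, mean 0.03, against a test that ranked them lower, and median -0.11 with median-ratio scaling, adjusted p = 0.0230), histones (-0.23, adjusted p = 0.0282) and exosome, SKI and TRAMP genes (-0.05, adjusted p = 0.0282). All 8 had adjusted p = 0.782 with an estimated correlation. RPL22B, RPL28 and RPS14B were the 3 of 108 ribosomal protein genes that rose, by 1.77, 1.13 and 0.95 on the log2 scale, and GLK1 was the 1 of 15 glycolysis genes that fell. In the other 6 lists limma called 0 members. At an unadjusted p under 0.05 these held 2 higher and 1 lower decapping gene, 2 higher mitochondrial ribosomal protein genes and 1 lower histone gene. The other lists held 0, and voom called 1 decapping and 1 mitochondrial ribosomal protein gene, both higher. Respiration (median 0.03, adjusted p = 0.131) and general stress genes (0.01, adjusted p = 0.436) had medians that differed in sign from their tests and turned to -0.08 and -0.10 with median-ratio scaling. Of 19 stress genes 5 were higher, led by SSA3 (2.37-fold), and 2 lower. limma called 0 of 32 respiration genes, with 0 at an unadjusted p under 0.05 and 0 by voom. It also called 0 of 6 phosphate and iron uptake genes, with 1 at an unadjusted p under 0.05 and 0 by voom (median -0.01, adjusted p = 0.357).

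Ribosomal protein and glycolysis genes also differed between libraries of one genotype. Over the WT mean, glycolysis medians were 0.82, -0.18 and -0.61 in upf2-delta and 0.26, 0.06 and -0.33 in WT, and ribosomal protein medians were 0.43, -0.15 and -0.45 in upf2-delta. Without upf2-delta replicate 3, 7 of the 8 lists ranked below the other mRNAs lost their call. Their medians were 0.17 (ribosomal proteins), 0.25 (glycolysis), 0.06 (translation factors), -0.06 (decapping), 0.08 (mitochondrial ribosomal proteins), -0.05 (histones) and 0.04 (exosome). Without upf2-delta replicate 1, 5 lost it: translation factors (-0.20), decapping (-0.19), exosome (-0.15), histones (-0.32) and ribosome biogenesis (-0.13). Without WT replicate 1, 4 lost it: glycolysis (0.07), translation factors (-0.07), mitochondrial ribosomal proteins (0.02) and histones (-0.15). In all, 13 of 21 lists passed, 8 without upf2-delta replicate 1 and 7 without upf2-delta replicate 3, and 0 passed with an estimated correlation. Higher features made up 97.1% of the calls, 65.8% with median-ratio scaling, 36.9% with quantile normalization and 74.5% with the added covariate.

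Loss of Upf3 raised many of the same transcripts. EST1, EST3 and EST2 rose 4.40-fold, 4.14-fold and 3.03-fold, with EST1 at a density of 2.38 ± 0.216 (SD, n = 3). RMD6 rose 23.5-fold, from 0.502 ± 0.0809 to 11.8 ± 0.509 (SD, n = 3), and REC107, TAH1 and MAK31 rose 12.4-fold, 11.1-fold and 10.1-fold. COX19, a factor for cytochrome oxidase assembly, rose 29.8-fold, SOM1 28.6-fold and ATP14, a subunit of the ATP synthase, 12.6-fold, and COX19 and ATP14 lost their calls with a covariate described below. FUS1, SDH5 and CLB1 fell by 1.93 ± 0.24, 1.5 ± 0.12 and 1.30 ± 0.17 on the log2 scale (SE), and SDH5 lies near the deleted UPF3. XUTs had a median of 1.01 (adjusted p = 3.14e-17, and adjusted p = 0.301 with an estimated correlation).

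In upf3-delta 2531 features were higher and 1095 lower than in WT, of which 1499 and 25 changed at least 2-fold. The counts were 2961 and 1841 with median-ratio scaling, 1847 and 3155 with quantile normalization and 790 and 686 with the main component of variation within genotypes as a covariate, a setting chosen after seeing the data. The lower count was 564 without WT replicate 2 and 639 without upf3-delta replicate 1. By class 1471 mRNAs were higher and 1010 lower, 540 XUTs were higher and 22 lower, 395 CUTs were higher and 20 lower, and 20 SUTs were higher and 8 lower. Of the tRNA features 86 were higher and 29 lower, or 46 and 22 over their 236 distinct positions, of the snoRNAs 7 and 6, and 12 of 14 rRNA features were higher. The libraries of both genotypes did not overlap for 60.9% of features with the snoRNA scaling (2979 higher, 1717 lower). By chance, with no offset common to many features, 10% would not. XUTs and CUTs (median 0.58) stood above the other features (adjusted p = 3.14e-17 and 1.87e-05, and adjusted p = 0.301 and 0.371 with an estimated correlation), and the CUT median turned to -0.06 with quantile normalization. rRNA features had a median of 2.73 (adjusted p = 0.0110, and adjusted p = 0.480 with an estimated correlation), a call lost with median-ratio scaling (2.74). Their share of reads did not rise, at 2.96% ± 0.570 in WT and 2.72% ± 0.347 in upf3-delta (SD, n = 3), and the 2 densest, rRNA-18130 and rRNA-20319, looked up after the values were seen, stood at -0.50 and -0.54 without passing. Their medians over the WT mean were 1.85, 2.17 and 3.16 in the upf3-delta libraries and 1.28 in upf2-delta 1. mRNAs had a median of -0.01 and a mean of 0.21 and ranked below the other classes (adjusted p = 7.94e-09, and adjusted p = 0.623 with an estimated correlation). SUTs and tRNAs did not pass, with medians of 0.06 and 0.30 (adjusted p = 0.211 and 0.511). The test ranked both lower, against their medians, which turned to -0.41 and -0.39 with quantile normalization.

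The other leading rises in upf3-delta were PRX1, a mitochondrial peroxiredoxin gene (17.8-fold, and 29.7-fold without WT replicate 1), MSW1, a mitochondrial tryptophanyl-tRNA synthetase gene (14.2-fold), and CAX4 (11.0-fold). COX19, ATP14, PRX1, MSW1 and CAX4 did not pass in upf2-delta, where their densities spread widely, as with ATP14 at 0.427 ± 0.392 (SD, n = 3) against 0.318 ± 0.159 in WT. COX19 lies opposite SUT016, MSW1 opposite CUT0665 and CAX4 opposite CUT0049. With the covariate these 5 genes lost their calls, with fitted changes of 1.20, 0.25, 0.93, 0.72 and 0.37 against 4.08, 3.63, 3.61, 3.45 and 3.42. Of the non-coding features, SUT067 rose by 3.58 ± 0.36 and CUT0224 by 3.16 ± 0.24 (SE). The rRNA features RDN58-2 and RDN25-2 rose by 3.69 ± 0.55 and 4.16 ± 1.13 (SE), the density of RDN25-2 was 8.29 ± 8.17 (SD, n = 3), and its direction turned with the covariate (-0.11), under which RDN58-2 lost its call (0.016). The ratio of RDN25-2 was 36.5, and 17.6 without upf3-delta replicate 3. Among falls, SDH5, an assembly factor of succinate dehydrogenase (chromosome 2, 970859 to 971335, 1 gene beyond the neighbour of UPF3), went from 0.873 ± 0.0678 to 0.289 ± 0.00370 (SD, n = 3; adjusted p = 5.08e-07). NRG1, FUS3, the mitochondrially encoded COX3, NOT5, GTT1 and KAR4 changed by log2 values from -1.04 to -0.88. Non-coding falls were led by the mitochondrial tRNA-4940 (-2.10 ± 0.55 SE), SUT006 (-1.86 ± 0.39 SE) and the mitochondrial tRNA-2926 (-1.55 ± 0.19 SE). The ratio of tRNA-4940 was 0.0939, 0.198 without WT replicate 1 and 0.0531 without upf3-delta replicate 2. With the covariate tRNA-4940 (-1.17), SUT006 (-1.40), COX3 (-0.56) and KAR4 (-0.76) lost their calls.

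**Figure D3:**
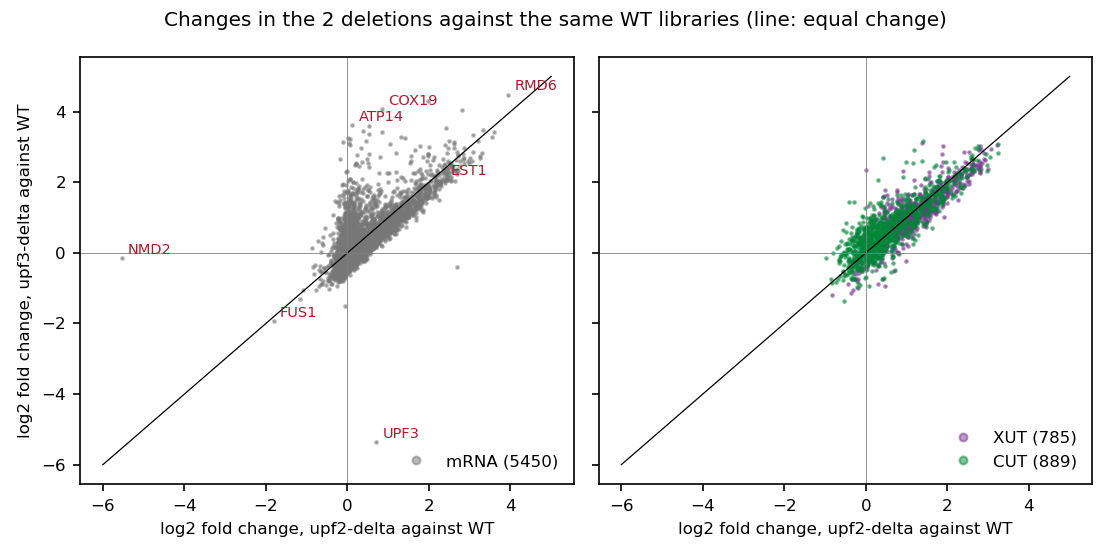
Log2 fold change against WT in upf2-delta (horizontal) and upf3-delta (vertical), with mRNAs in one panel, XUTs and CUTs in the other, and a line of equal change. Over all tested features the values correlated with r = 0.787, and the points of the deleted genes are fitted values, not bounds.

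Known NMD targets rose in 8 of 9 cases in upf3-delta (median 1.39, adjusted p = 0.000106, and adjusted p = 0.898 with an estimated correlation). Galactose and allantoin genes rose in 7 of 10 cases (median 1.36, adjusted p = 0.00200, and adjusted p = 0.898 with an estimated correlation), with DAL3, DAL5, DAL7 and DAL1 between 5.98-fold and 9.19-fold. GAL80, the 1 member that fell (-0.49), was looked up after the counts were seen. Meiosis and sporulation genes rose in 9 of 17 cases (median 0.64, adjusted p = 0.00340, and adjusted p = 0.898 with an estimated correlation), with SPO22 at 6.07-fold and HOP2 at 7.48-fold, while quantile normalization ended the list's call and turned its median to -0.09. Telomere genes rose in 6 of 11 cases, 7 when adjusted over the list alone, and RAP1, looked up for the same reason, fell (-0.34). That list's median was 0.68 (adjusted p = 0.0256, and adjusted p = 0.898 with an estimated correlation), a call lost with median-ratio scaling (0.69) and with quantile normalization (0.08). Other amino acid genes rose in 18 of 35 cases and fell in 1, or 20 and 1 when adjusted over the list alone (median 0.44, adjusted p = 0.00264, and adjusted p = 0.898 with an estimated correlation). MET16 rose 8.69-fold, MET3 2.53-fold and the lysine genes LYS9 and LYS4 2.48-fold and 2.45-fold, and with the added covariate MET3 (0.52) and LYS9 (0.37) lost their calls. Ribosome biogenesis genes fell in 8 of 29 cases and rose in 1 (median -0.23, adjusted p = 0.00431, and adjusted p = 0.898 with an estimated correlation, a call also lost with quantile normalization at -0.31), with NOP56 at -0.49 ± 0.14 and NOC2 at -0.48 ± 0.13 (SE). Both lost their calls with the added covariate (-0.49 and -0.55). Glycolysis genes rose in 11 of 15 cases (median 1.15, adjusted p = 0.0256, and adjusted p = 0.898 with an estimated correlation), with ADH1 at 6.18-fold, TDH2 at 3.01-fold and PGK1 at 2.51-fold. The glycolysis call was lost without WT replicate 2 (1.15), without WT replicate 3 (0.99) and without upf3-delta replicate 1 (1.21), and with the added covariate its median turned to -0.69, and ADH1 (-0.71), TDH2 (-0.51) and PGK1 (-0.64) turned too. Its medians over the WT mean were 1.04, 1.19 and 1.18 in upf3-delta, near the 0.82 of upf2-delta 1.

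**Figure D4:**
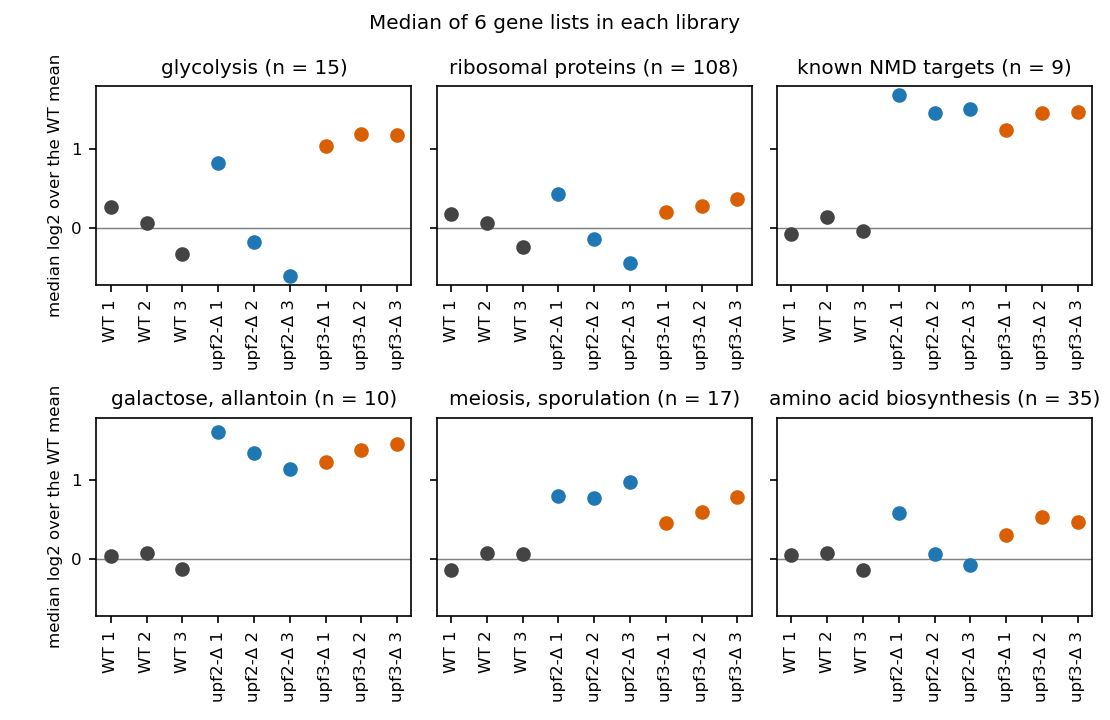
Median log2 density of 6 gene lists in each library, over the WT mean. Glycolysis medians were 0.82, -0.18 and -0.61 in upf2-delta and 1.04, 1.19 and 1.18 in upf3-delta, and quantile normalization turned the upf3-delta change of meiosis and sporulation genes from 0.64 to -0.09.

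The other lists did not pass in upf3-delta, while single members did. Many of these members varied within genotypes, and with the added covariate the direction turned for RPL43B (-0.43), RPS3 (-1.06), RIP1 (-0.25), CYT1 (-0.26), MRPL20 (-1.17), HYP2 (-0.014), HHO1 (-0.57), RRP40 (-0.61) and PHO84 (-0.14). The covariate also lowered the median of all mRNAs from -0.01 to -0.38, so RIP1, CYT1, HYP2 and PHO84 still lay above the typical mRNA. The upf3-delta libraries all lie at one end of this component, so the covariate also takes up genotype. Ribosomal protein genes had 24 of 108 members higher and 7 lower, or 21 and 5 when adjusted over the list alone (median 0.28, adjusted p = 0.196), with RPP2A and RPL43B at 8.43-fold and 7.89-fold and RPS3 at 4.64-fold. RPL43B was 12.2-fold higher without WT replicate 1, and RPP2A lost its call with the covariate (0.65). That list passed without WT replicate 1 (0.38), and with the added covariate its direction turned (-0.86). Decapping genes had 9 of 19 lower, such as LSM4 (-0.82 ± 0.13 SE, call lost with the covariate at -0.48), and 3 higher, such as DCP1 (2.93-fold, turned to -0.081 with the covariate) and LSM1 (2.55-fold, turned to -1.09), or 10 and 4 when adjusted over the list alone (median -0.26, adjusted p = 0.0581). It passed without WT replicate 2 (-0.22) and without upf3-delta replicate 1 (-0.23). Arginine genes rose in 4 of 7 cases (median 0.95, adjusted p = 0.0581), ARG8 by 3.62-fold and CPA1 by 2.62-fold, and pyrimidine genes in 4 of 7 (median 0.77, adjusted p = 0.0913), URA3 by 2.34-fold (call lost with the covariate at 0.52). With quantile normalization both lists passed (0.83 and 0.69). General stress genes had 8 of 19 higher and 4 lower (median 0.12, adjusted p = 0.816), with SOD1 at 3.93-fold (turned to -0.85 with the covariate), HSP12 at 3.37-fold (call lost at 0.54) and TPS1 at 3.02-fold (turned to -0.64), and the median turned to -0.16 with quantile normalization. Respiration genes had 8 of 32 higher and 3 lower, or 7 and 2 when adjusted over the list alone (median 0.05, or -0.01 with quantile normalization, adjusted p = 0.816), with RIP1 at 2.62-fold and CYT1 at 2.24-fold. Mitochondrial ribosomal protein genes had 9 of 66 higher and 9 lower, or 7 and 8 when adjusted over the list alone (median -0.11, mean 0.02, adjusted p = 0.148), with MRPL20 at 2.64-fold. Translation factor genes had 1 of 19 higher, HYP2 at 3.31-fold, and 1 lower, or 1 and 0 when adjusted over the list alone (median -0.13, mean 0.10, adjusted p = 0.585). Histone genes had 1 of 8 higher, HHO1 at 2.87-fold, and 1 lower, HTB1 at -0.47 (median 0.06, or -0.23 with quantile normalization, against a test that ranked them lower, adjusted p = 0.829). HTB1 lost its call without WT replicate 2 (-0.44), WT replicate 3 (-0.42), upf3-delta replicate 1 (-0.42) or upf3-delta replicate 2 (-0.49). Exosome genes had RRP40 higher (1.95-fold) and 2 of 20 lower, or 1 and 0 when adjusted over the list alone (median -0.20, adjusted p = 0.0994). STE2, BAR1 and STE6 rose 2.83-fold, 2.27-fold and 1.40-fold, and AGA2 fell by 0.79, a call lost without WT replicate 1 (-0.75), WT replicate 2 (-0.70) or any upf3-delta replicate (-0.82, -0.81 and -0.75; a-specific list median 0.75, adjusted p = 0.224). BAR1 lost its call with the covariate (0.53) and with quantile normalization (0.20), and STE6 with the covariate (0.26). Of the alpha-specific genes 1 of 3 was higher, or 1 higher and 2 lower when adjusted over the list alone (median -0.36, adjusted p = 0.667). Phosphate and iron uptake genes had PHO84 higher and FTR1 and PHO81 lower (median -0.17, adjusted p = 0.336). PHO84 lost its call without WT replicate 2 (0.37), WT replicate 3 (0.36), upf3-delta replicate 2 (0.38) or upf3-delta replicate 3 (0.40), and with quantile normalization (0.16). FTR1 lost its call without WT replicate 2 (-0.41), upf3-delta replicate 1 (-0.45) or upf3-delta replicate 2 (-0.58), and with the covariate both FTR1 (-0.66) and PHO81 (-0.39) did. Of the NMD factors NMD4 rose 2.36-fold and EBS1 1.37-fold (call lost with the covariate at 0.45), NAM7 stood at 0.28 ± 0.12 (SE) without passing, and UPF3 was absent (median 0.28 with UPF3 fitted or at its bound, mean -0.71, adjusted p = 0.829). That list test includes the deleted UPF3. Higher features made up 69.8% of the calls, 61.7% with median-ratio scaling, 36.9% with quantile normalization and 53.5% with the covariate.

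Between the deletions, 8 of 15 glycolysis genes, 12 when adjusted over the list alone, and 14 of 108 ribosomal protein genes were higher in upf3-delta, and 1 ribosomal protein gene was lower. Both list calls were lost with an estimated correlation (adjusted p = 0.978), quantile normalization ended the ribosomal protein call and the added covariate turned its direction (-0.50). ADH1 was 6.14-fold and TDH2 3.01-fold higher in upf3-delta than in upf2-delta, and without upf2-delta replicate 1 these were 12-fold and 4.74-fold. RPP2A, a protein of the ribosomal stalk, was 8.33-fold higher (log2 3.24 ± 0.36 SE, adjusted p = 0.000369), and ATP14 9.36-fold (3.51 ± 0.48 SE, adjusted p = 0.00168). Without upf2-delta replicate 1 they were 13.1-fold and 19.5-fold higher. SDH5, 1 gene beyond the neighbour of the deleted UPF3, was lower by 1.44 ± 0.12 in upf3-delta (SE; adjusted p = 3.33e-05). The telomerase gene EST2 was 1 of 2 known NMD targets that were lower in upf3-delta (-0.52 ± 0.11 SE, adjusted p = 0.0190).

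In all 411 features were higher and 502 lower in upf3-delta than in upf2-delta, and 268 and 16 differed at least 2-fold. Among mRNAs 295 were higher and 446 lower, among XUTs 16 and 25, among CUTs 33 and 19, among SUTs 9 and 1, and among tRNA features 46 and 11, or 24 and 10 over their 236 distinct positions. For rRNA features 10 of 14 were higher, and for snoRNAs 2 of 37. The libraries of both deletions did not overlap for 38.9% of features (676 higher, 2325 lower), against 10% by chance. That chance share assumes no offset common to many features. The mRNA median was -0.16, or -0.04 with median-ratio scaling, and the share was not computed with other scalings. Higher features made up 45.0% of the calls, and both counts and share depended on the setting. Higher and lower features numbered 1165 and 831 with median-ratio scaling (58.4% higher), 932 and 1572 with quantile normalization (37.2%), 560 and 266 with the replicate block (67.8%), 223 and 117 without a trend (65.6%) and 176 and 57 with only the 6 libraries compared (75.5%). Under settings chosen after seeing the data they were 29 and 74 with the covariate (28.2%), 45 and 8 with the covariate and median-ratio scaling (84.9%) and 1225 and 588 without WT replicate 1 and upf2-delta replicate 1 together (67.6%). Without upf3-delta replicate 1 the share was 87.0%. RDN58-2 was higher by 3.82 ± 0.55 (10.8-fold, and 23.8-fold without upf2-delta replicate 1) and the mitochondrial tRNA-2926 and tRNA-9219 lower by -1.54 ± 0.19 and -1.52 ± 0.26 (SE). XUT0007 was lower by -1.42 ± 0.26 (SE), a call lost without upf3-delta replicate 1 (-1.29) and with the added covariate (-1.64), and its ratio of 0.267 was 0.163 without upf3-delta replicate 2. Ranked by camera, tRNAs (median 0.45), rRNA features (2.22), SUTs (0.11) and CUTs (0.05) were higher in upf3-delta (adjusted p = 4.01e-14, 2.32e-09, 0.000219 and 0.000108), and quantile normalization turned the CUT median to -0.07. The mRNA median was -0.16 (adjusted p = 5.00e-07). With an estimated correlation these 5 classes had adjusted p = 0.273, 0.219, 0.273, 0.279 and 0.589. Over the WT mean, tRNA medians were 0.28, 0.05 and -0.76 in the upf2-delta libraries and 0.32, 0.42 and 0.36 in upf3-delta. Much of the tRNA difference thus came from upf2-delta 3, while upf2-delta 1 lay near upf3-delta. Shares of reads did not rise for rRNA (2.81% ± 0.163 in upf2-delta, 2.72% ± 0.347 in upf3-delta), SUTs (4.79% ± 0.509, 4.42% ± 0.287) or CUTs (0.497% ± 0.0372, 0.443% ± 0.0184; SD, n = 3), while that of tRNAs went from 0.0294% ± 0.00555 to 0.0479% ± 0.00165 (SD, n = 3). XUTs (-0.08, or 0.02 with median-ratio scaling) did not pass (adjusted p = 0.430), and the test ranked them higher, against their median.

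Of the lists, 6 of 21 passed between the deletions, all with adjusted p = 0.978 with an estimated correlation. Glycolysis (median 1.08, adjusted p = 2.17e-11) and ribosomal proteins (median 0.31, adjusted p = 3.34e-12) were higher, without passing with an estimated correlation (adjusted p = 0.978). When adjusted over the list alone, 16 ribosomal protein genes were higher and 1 lower. The ribosomal protein median was 0.01 with quantile normalization. Other amino acid genes (median 0.20, adjusted p = 1.29e-05, and adjusted p = 0.978 with an estimated correlation) had 4 of 35 higher, or 8 higher and 1 lower when adjusted over the list alone. Respiration (median 0.02, adjusted p = 0.0201, and adjusted p = 0.978 with an estimated correlation) had 4 of 32 higher and 1 lower, or 7 and 1 when adjusted over the list alone, and lost its call without upf2-delta replicate 1 (0.11) and without upf2-delta replicate 2 (-0.05). Histones (median 0.19, or -0.07 with quantile normalization, adjusted p = 0.0329, and adjusted p = 0.978 with an estimated correlation) had HHO1 higher, or 2 of 8 when adjusted over the list alone, and lost their call without upf2-delta replicate 1 (0.34) and without upf2-delta replicate 3 (0.07). Meiosis genes were lower, 4 of 17 with a median of -0.36 (adjusted p = 0.0375, and adjusted p = 0.978 with an estimated correlation), with SPO22 at -0.45 ± 0.11, RED1 at -0.59 ± 0.17 and MSH4 at -0.41 ± 0.12 (SE). That call was lost without upf2-delta replicate 1 (-0.31), without upf2-delta replicate 3 (-0.36) and without upf3-delta replicate 3 (-0.38). Without upf2-delta replicate 1, 3 lists passed. Per library, upf2-delta 1 lay near upf3-delta for these groups: its ribosomal protein median over the WT mean was 0.43, against 0.20, 0.28 and 0.36 in upf3-delta, and its other amino acid median was 0.58, against 0.31, 0.54 and 0.47.

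The count of differences between the deletions rested on single libraries. It was 1792 without upf2-delta replicate 1, 537 without WT replicate 3, 349 without upf2-delta replicate 3, 260 without upf3-delta replicate 3, 159 without upf3-delta replicate 2, 120 without upf2-delta replicate 2 and 100 without upf3-delta replicate 1. Higher features numbered 1216 without upf2-delta replicate 1, 267 without WT replicate 2, 254 without upf2-delta replicate 3, 143 without upf3-delta replicate 3, 129 without upf3-delta replicate 2, 104 without upf2-delta replicate 2 and 87 without upf3-delta replicate 1. Lower features numbered 196 without WT replicate 3, 117 without upf3-delta replicate 3, 95 without upf2-delta replicate 3, 30 without upf3-delta replicate 2, 16 without upf2-delta replicate 2 and 13 without upf3-delta replicate 1.

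Of the 2020 features higher in upf2-delta 1723 were also higher in upf3-delta, and with the added covariate 772 of 1906. EST1, DAL5, SPO22, REC107, RMD6, CPA1 and STE2 rose in both, and FUS1, FUS3, CLB1, NRG1, GTT1 and KAR4 fell in both. In all 1723 features were higher in both deletions, among them 972 mRNAs, 459 XUTs and 282 CUTs, and 85.3% of those higher in upf2-delta were higher in upf3-delta. Independent calls of these sizes would share 663, a number that leaves out the shared WT libraries. Lower in both were 37 features, against 8.52 for independent calls, and this count was 856 with median-ratio scaling, 2161 with quantile normalization and 369 with the covariate. The lower count was 19 without WT replicate 2, 21 without upf2-delta replicate 2 and 70 without upf2-delta replicate 1. Opposite calls numbered 4. Across features, which are not independent replicates, fold changes correlated with r = 0.787, against 0.498 in simulations of unchanged groups that shared a simulated WT group. Their covariance was 0.426 against 0.0271, a difference of 0.399. The sign was the same for 76.4% of features, against 66.7% in the simulations. The simulated noise was independent across features, without the component of variation shared within genotypes. Agreement which that component may bring is thus not in the simulated values. The 3 WT libraries cannot be split into parts of at least 2, so part of the excess may come from the shared controls.

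mRNAs with a non-coding partner on the opposite strand were higher than other mRNAs in both deletions. In upf2-delta the median was 0.17 over 850 partner mRNAs and 0.02 over 4600 others, a difference of 0.15. In upf3-delta the medians were 0.25 and -0.05, a difference of 0.29. Both differences had a two-sided permutation p of 1e-05, the smallest these resamples can give, also after adjustment over 4 tests. Across 1112 pairs the changes of both strands correlated with a Spearman rho of 0.134 in upf2-delta and 0.143 in upf3-delta (permutation p = 1e-05 for each, the smallest possible). These permutations treat mRNAs and pairs as independent, though all values come from the same libraries and pairs can share an mRNA or reads. Their p-values therefore do not measure the spread between libraries. Of 518 pairs whose non-coding member was higher in upf2-delta, the mRNA was higher in 219 and lower in 3. Of 638 such pairs in upf3-delta, it was higher in 282 and lower in 62. URA10 rose with CUT0569 and XUT0433, which overlap each other, and STE2 rose with XUT0490, while FUS1 fell as XUT0415 opposite it rose (log2 1.75 and 1.83 in the 2 deletions). These non-coding partners were looked up after their values were seen. The strand setting of the counting is not given, so reads of overlapping opposite strands may not have been told apart.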

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

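The settings added after seeing the data were voom on the recovered reads, the main component of variation within genotypes as a covariate (alone and with median-ratio scaling), 1 feature per position, and WT 1 and upf2-delta 1 left out together. Direction here means the sign of a value, but for feature classes and gene lists the direction of the test against the other features, so a median can change sign while its test does not turn. Quantile normalization did this to the CUT medians (0.40 to -0.13 in upf2-delta and 0.58 to -0.06 in upf3-delta), whose tests still passed. Under the planned settings other than leaving out a library, main results kept their direction and side of the threshold, and counts stayed within 1.5 times, in 186 cases. In these settings 33 moved, 5 kept their direction but lost the threshold and 0 reversed. With a library left out the numbers were 184, 30, 2 and 0, and under the added settings 99, 21, 0 and 0. Values of named genes were the same in 1944 planned cases, with 18 weaker and 0 reversed, and 80 were weaker and 32 reversed under the added settings. Single gene lists were the same in 562 planned cases, with 44 weaker and 3 reversed. The cause was not tested for any change below, except where fewer libraries, a stricter threshold or a different scaling acts by construction. upf3-delta had the fewest reads, from 25143181, and thinning all libraries to the smallest total is described in the next part.

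With a threshold of 0.01, which calls fewer features by construction, upf2-delta against WT had 22 lower features. upf3-delta against WT had 2402 in all and 502 lower, and upf3-delta against upf2-delta 99 (88 higher, 11 lower). With an estimated correlation the medians are the same by construction and the calls were lost: XUT 1.00 and 1.01, CUT 0.40 and 0.58, and 0, 0 and 0 gene lists in the 3 comparisons. With no filter the CUT call in upf2-delta was lost (0.22).

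Median-ratio scaling over coding features gave 3169 features in upf2-delta against WT (1083 lower), 1841 lower in upf3-delta against WT, 1996 between the deletions (1165 higher, 831 lower) and 856 lower in both. Quantile normalization gave 4165 in upf2-delta (2627 lower), 3155 lower in upf3-delta, 2504 between the deletions (932 higher, 1572 lower) and 2161 lower in both. Under it 8 lists passed in upf2-delta, and the test's direction reversed for snoRNAs (-0.011, the class whose median the main scaling holds near 0), translation factors (-0.041), glycolysis (-0.010) and ribosomal proteins (-0.026). The replicate number as a block left 8 lists in upf2-delta, and between the deletions 266 lower features and 3 lists. The labels give no pairing and the numbers were not treated as pairs. Residuals of WT and upf2-delta with the same number correlated with r = 0.717, 0.00207 and 0.509, those involving upf3-delta were near 0, and 6 of 9 libraries correlated best with a library of their own number. Without a trend, 340 features differed between the deletions (223 higher, 117 lower), and with only the 6 libraries compared 233 (176 higher, 57 lower).

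With the added covariate, 653 features were lower in upf2-delta, 1476 differed in upf3-delta (790 higher, 686 lower) and 103 between the deletions (29 higher, 74 lower). The median of all mRNAs went from -0.01 to -0.38 in upf3-delta against WT and from -0.16 to -0.37 between the deletions. Reversals to values above these medians can come from that shift alone. There 3 lists passed between the deletions, and 772 features were higher and 369 lower in both. Its reversed lists were glycolysis (-0.69) and ribosomal proteins (-0.86) in upf3-delta against WT, and meiosis (-0.35) and ribosomal proteins (-0.50) between the deletions, where meiosis reversed by its test. Reversed genes were LSM1 in upf2-delta (-0.38), and in upf3-delta RDN25-2 (-0.11), DCP1 (-0.081), LSM1 (-1.09), RRP40 (-0.61), ARG1 (-0.025), HHO1 (-0.57), HYP2 (-0.014), TEF2 (-0.82), EFT2 (-0.86), ADH1 (-0.71), TDH2 (-0.51), FBA1 (-0.51), PGK1 (-0.64), RIP1 (-0.25), CYT1 (-0.26), SDH1 (-0.11), ATP2 (-0.42), SOD1 (-0.85), TPS1 (-0.64), PHO84 (-0.14), AFB1 (-0.27), RPL43B (-0.43), RPS3 (-1.06), RPS21A (-0.73), MRPL20 (-1.17), MRPL28 (-0.24), MRP20 (-0.70) and MRPS35 (-0.66). With the covariate and median-ratio scaling, 4258 features differed in upf2-delta (1935 lower), 53 between the deletions (45 higher, 8 lower), and 830 were lower in both. Reversed there were glycolysis (0.054, by its test) and ribosomal proteins (-0.32) in upf3-delta, LSM1 (-0.18), EFT2 (-0.25) and MRPL20 (-0.25), and between the deletions ribosome biogenesis (0.060), meiosis (-0.011) and ribosomal proteins (-0.14). With WT 1 and upf2-delta 1 left out together, 153 features were lower in upf2-delta, 1813 differed between the deletions (1225 higher), 3 lists passed there and 76 features were lower in both.

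With each library left out in turn, the lowest and highest values were 35 and 209 for lower features in upf2-delta, 0.31 and 0.45 for its CUT median, 7 and 13 for its lists, and 0.57 and 0.74 for its NMD factor median, whose test reversed without upf2-delta replicate 3. For upf3-delta they were 564 and 1375 lower features. Between the deletions they were 100 and 1792 features, 87 and 1216 higher, 13 and 576 lower, and 3 and 7 lists. For features lower in both they were 19 and 70. Ranges of results that stayed the same were 1814 to 2212 features in upf2-delta and 2775 to 4240 in upf3-delta, XUT medians of 0.93 to 1.04 and 0.97 to 1.05, and 1511 to 1876 features higher in both.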

Other observations

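Tests chosen after the result was seen were the 2 gene lists of the next paragraph, the comparison of WT libraries, the like-length comparison, the tests of genes beside the deletions, and the tests of adjacent mRNAs.

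FUS1, FUS3 and KAR4 fell in both deletions, and a list of 25 pheromone response genes was written after those falls were seen. It did not pass in upf2-delta (6 higher, 7 lower, adjusted p = 0.0689) or upf3-delta (5 higher, 11 lower, adjusted p = 0.0501). KSS1, a MAP kinase related to FUS3, rose by 0.94 ± 0.13 in upf2-delta and 0.54 ± 0.13 in upf3-delta (SE). COX3 fell by 0.46 ± 0.15 in upf2-delta and 1.02 ± 0.15 in upf3-delta (SE), and ATP6 fell by 0.75 ± 0.15 in upf3-delta (SE). A list of 7 mitochondrially encoded mRNAs, also written afterwards, had 4 lower in upf3-delta (median -0.59, adjusted p = 0.02, and p = 0.209 with an estimated correlation), and did not pass in upf2-delta (1 lower, adjusted p = 0.0689).

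The mRNAs higher in upf3-delta than in upf2-delta numbered 295, with a median change of 1.12, among them ADH1, RPP2A and ATP14. Of these, 91.2% were higher in WT 1 than in WT 3, against 47.8% of other mRNAs, so the same mRNAs also varied between libraries of one genotype. After thinning every library to the smallest read total their median was 1.11. Thinning keeps the density of each feature on average, so this median could hardly change and does not decide on read depth. The members were shorter than other mRNAs, with median lengths of 789 and 1284 nt. mRNAs of like length had a median change of -0.11, so length alone did not bring the rise, while a factor linked to length stays open. A factor of the libraries, such as growth state or RNA handling, may contribute, or loss of Upf3 itself. The 3 upf3-delta libraries all lie at one end of this component (scores of 1.09 to 1.14, with upf2-delta 1 at 0.45 and the others below 0), so genotype and component cannot be separated here, and new cultures grown in mixed order would test it.

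Of the 4 genes flanking the deleted genes, NCAS0H01730 beside NMD2 rose by 2.70 ± 0.13 in upf2-delta and fell by 0.40 ± 0.13 in upf3-delta (SE). THP1 beside UPF3 rose by 1.79 ± 0.13 in upf3-delta (SE) and not in upf2-delta (0.21), while PTC7 and SMD1 were not called. SDH5, the gene beyond THP1, fell in upf3-delta and was not counted among the 4 flanks. In all 2 of 4 were called between the deletions, which argues against loss of either factor acting alike on these genes. A local effect of each deletion could explain them, yet random flanks held as many with a permutation p of 0.091 (0.54 called on average). The bound written for this test, that a p of 0.05 or more would count against a local effect, was wrong, since 4 flanks are too few and a missed threshold excludes nothing, so a local effect stays open.

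TAH1 with TVS1, SLO1 with ISC10 and DAL3 with DAL7 are tandem neighbours that rose together, and such pairs, all of them tandem, prompted a test of adjacent mRNAs in upf2-delta that also counts them and so partly restates its prompt. Among adjacent pairs with at least 1 higher member, both were higher in 18.0% of tandem, 15.0% of divergent and 12.8% of convergent pairs. Tandem pairs stood 4.10 points above the other 2 kinds together (one-sided permutation p = 0.0065, adjusted p = 0.013 over 2 tests). The changes of divergent neighbours correlated as strongly as those of tandem neighbours (Spearman rho of 0.0998 and 0.0865, and -0.0153 for convergent ones). The correlation thus did not set tandem pairs apart, which neither favours nor excludes reading through from a gene into its tandem neighbour. Tandem pairs with both higher numbered 180, against 128 for random pairs, which was not tested and includes the pairs that prompted it. Non-tandem pairs with both higher numbered 148, against 139 for random pairs (permutation p = 0.24), a missed threshold that excludes nothing. The bounds written for both tests were therefore wrong, since the first lumped divergent with convergent pairs and the second took a missed threshold as exclusion. Median gaps also differed, at 365, 472 and 171 nt for tandem, divergent and convergent pairs, and were not matched. Transcription between tandem neighbours and an effect of position whatever the orientation could each contribute, and both stay open.

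Other splits of the same 6 libraries number 10 with the real one, too few for a share under 0.05. In upf2-delta against WT 1 of 10 splits called as many features (2080, highest other 2), 1 gave an XUT median as large (1.00, highest other 0.44) and 1 as many lists (13, highest other 11). For upf3-delta against WT the numbers were 1 (3626, highest other 0), 1 (1.01, highest other 0.43) and 4 for lists (7, highest other 9). Between the deletions they were 1 for features (913, highest other 1) and 1 for lists (6, highest other 5). For features higher in both deletions, 1 of 100 splits of the 9 libraries gave as many (1723), a share under 0.05. The highest others, 1577 and 1584, kept the 3 WT libraries together and mixed the deletions, and the remaining 97 gave at most 179. The share therefore tells WT from the other libraries and does not test sharing between the deletions.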
